A study of Arabidopsis thaliana with 2 samples.

How the data were processed

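Small RNA libraries were made from total RNA of unopened flower buds with an Illumina small RNA kit, per the labels' protocols, 1 from wild-type and 1 from dcp5-1 plants grown on soil. The authors deposited, for each library, a table of distinct sequences with the count of reads and the length of each, and a table of genome hits with position, strand and number of mismatches. The deposited counts are raw numbers of reads per sequence, not normalised. The submitters' processing notes name the genome build TAIR 9. The adapter trimmer and the aligner are not given in the sources used here. Lengths ran from 16 to 30 nt and listed hits had up to 2 mismatches, so sequences outside these limits could not be counted.

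Only each sequence's hits without a mismatch and lengths of 18 to 28 nt were used; this limit on mismatches was set after the layout of the files was seen and before class results. The deposited tables hold no bases, so sequences were read from the TAIR10.1 reference at these hits. The nuclear coordinates were checked against it: among 20000 multi-hit sequences drawn per library, all 124674 pairs of hits in wild type and all 126431 in dcp5-1 had identical bases. The mitochondrial reference is another sequence and gave no bases or genes. A read with several hits gave each hit its count divided by the number of hits; 69.8% of the reads in wild type and 72.5% in dcp5-1 had 1 hit. Reads that matched nowhere were 19.5% of all reads in wild type and 22.8% in dcp5-1.

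Hits were assigned by their midpoint to the 37899 annotated nuclear genes, on each strand, to 5-kb windows and to 100-kb windows. As the reference has practically no transposable element annotation, the alternative fixed before the data were examined was used, 24-nt reads in gene-poor windows (163 of 1193); the limit of 10 protein-coding genes that defines them was set after the reference was seen. Most of the 45S and 5S rRNA repeats are not annotated there, so reads within 8 kb of an annotated rRNA gene were kept apart from structural RNA, a choice also made after the reference was seen. Mature miRNA reads were those identical to 73 listed sequences, each found in a MIR gene of its own number; of 13 listed passenger strands 12 were. Reads from near-identical gene copies cannot be assigned with certainty, and overlapping genes share reads.

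Log2 ratios are dcp5-1 over wild type of reads per 1000000 perfect reads of 18 to 28 nt (RPM). Printed ratios and their intervals were computed from weighted counts rounded to whole reads, ties going to the even number; 0.5 was added to each count for rankings, counts of genes past 2-fold and list medians. Intervals are exact conditional binomial (Clopper-Pearson) for ratios and Wilson for shares, at 95%. Reads amplified by PCR without molecular identifiers are not independent molecules. Gene lists (11) and the miRNA list were written before the data were examined, as were the comparisons, minimums and naming rule. Members with fewer than 20 reads were not measured, and a list's median was placed among 10000 random lists matched on mean level in 10 classes. For the gene lists these were drawn from nuclear genes of all types with at least 20 reads, without a match on gene type or read size. Among genes with at least 100 reads, the median log2 ratio was 0.30 for pseudogenes, 0.041 for protein-coding genes and -0.87 for tRNA genes. A percentile can therefore partly reflect gene type. Items were named from each list and from the miRNAs among the 4 measured members with the highest level and the 3 with the largest change, with all TAS loci and DCP5; outside the lists, structural RNA left out, among the 8 highest and 8 lowest genes and the 5 highest and 5 lowest windows with at least 500 reads. Other named items are said to be chosen after their values were seen, or are unmeasured list members.

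On simulated counts for 5647 genes, with 200 changed 4-fold, 100% of the changed genes were recovered as at least 2-fold and 95.4% of the intervals held the true ratio. The simulated counts were Poisson draws without PCR duplication or variation between libraries, so they checked the calculation only. The alternatives tried were scaling to all reads, to reads outside structural RNA and organelles or by edgeR TMM factors, only 1-hit reads or full counts at every hit, distinct sequences with the dcp5-1 library thinned, leaving out the most abundant sequence, miRNA isoforms and other minimums. Added after seeing the data were hits with up to 2 mismatches, structural RNA with rRNA flanks, ratios from counts that were not rounded, and every count of protein-coding genes by 21-nt reads. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.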

Results

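Small RNA was sequenced from unopened flower buds of Arabidopsis thaliana, 1 library from wild-type Col-0 plants and 1 from the dcp5-1 mutant. DCP5 is a protein of the mRNA decapping machinery that locates to cytoplasmic P-bodies. The comparison asks how the small RNA population of flower buds differs when DCP5 is mutated. The wild-type library held 11446740 reads of 4295821 distinct sequences and the dcp5-1 library 14881275 reads of 6143873 distinct sequences. Reads of 18 to 28 nt that matched the genome without a mismatch numbered 7645212 in wild type and 9812557 in dcp5-1, and levels are given in reads per 1000000 of these (RPM). Coordinates are those of the TAIR10.1 reference annotation. With 1 library per genotype no difference has a replicate check, so no p-value is given. The 95% intervals in brackets are exact conditional binomial intervals for ratios and Wilson intervals for shares, and they cover counting error only. The DCP5 gene itself (AT1G26110, chromosome 1, 9024341 to 9027955) had 2.08 weighted reads in wild type and 5.04 in dcp5-1. Small RNA reads do not measure its mRNA, so these values do not check the genotype labels.

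To see how the size classes differed, reads were counted by length. The 24-nt class, the size of heterochromatic siRNAs, made up 61.5% of the reads in wild type and 67.2% in dcp5-1, a log2 ratio of dcp5-1 over wild type of 0.13 (0.13 to 0.13). The 21-nt class, the size of most miRNAs and ta-siRNAs, made up 8.67% and 7.70%, a log2 ratio of -0.17 (-0.18 to -0.17). Of the lengths from 18 to 28 nt, the 20-nt class had the lowest ratio, at -0.79 (-0.80 to -0.78). Among 24-nt reads, 54.7% began with A in wild type and 52.6% in dcp5-1. The direction of the 24-nt difference depended on the scaling: it was -0.033 with edgeR TMM factors, which moved every log2 ratio by -0.16 and the median of all measured genes from 0.13 to -0.027. When distinct sequences were counted at equal depth in place of reads, the 21-nt ratio was 0.13.

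**Figure D1:**
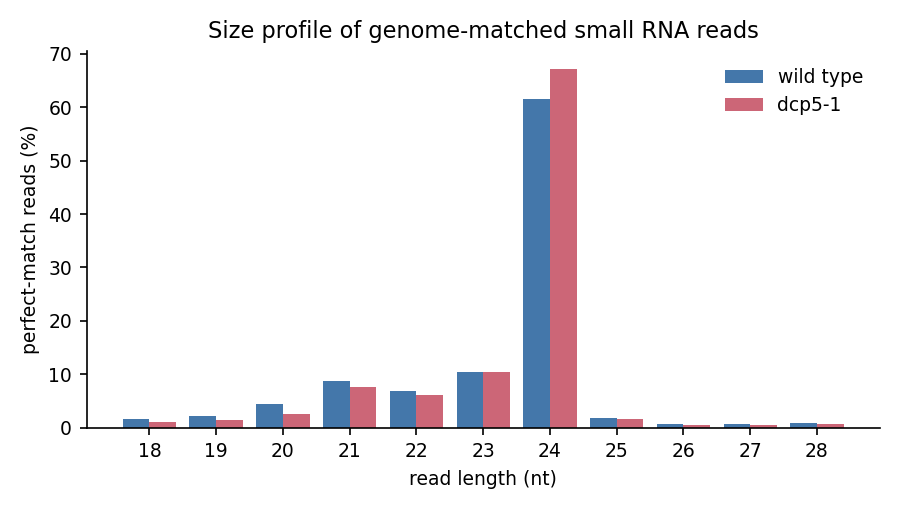
Bars give the percentage of perfect-match reads of 18 to 28 nt at each length (x axis, nt) in the wild-type and dcp5-1 libraries. The 24-nt bar stands at 61.5% in wild type and 67.2% in dcp5-1, and the 21-nt bars at 8.67% and 7.70%.

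Reads of annotated structural RNA genes and of the organelle genomes were counted as a measure of RNA fragments in each library. Structural RNA reads (rRNA, tRNA, snRNA and snoRNA genes) were lower in dcp5-1, with a log2 ratio of -0.51 (-0.51 to -0.50), at 44576 RPM in wild type and 31410 in dcp5-1. Chloroplast reads had a log2 ratio of -1.17 (-1.18 to -1.16) and mitochondrial reads one of -0.96 (-0.97 to -0.94). Of the 9 measured nuclear photosynthesis genes, whose mRNA is abundant in leaves and sepals, 8 were lower in dcp5-1 and 1 was higher. Their median log2 ratio of -0.53 lay at percentile 1.77 of 10000 random gene lists matched on mean level but not on gene type. LHCB2.1 (-0.53, -1.03 to -0.027), at the middle of the list, had mostly 24-nt reads. These were 43.1 of 73.9 weighted reads in wild type and 45.1 of 65.5 in dcp5-1. Its ratio, and so the list median, does not measure mRNA fragments alone. The RBCS and CAB genes share multi-hit reads with similar copies, so these members are not independent, and the tally and the percentile rest on fewer separate values than 9. RBCS1B (-1.54, -2.72 to -0.47) and RBCS3B (-1.48, -2.40 to -0.62), which encode small subunits of Rubisco, were among the lowest. CAB1, a chlorophyll-binding protein gene that overlaps another gene, was higher (1.13, 0.28 to 2.05). It had 6.78 weighted 21-nt reads in wild type and 29.15 in dcp5-1, and 43.1% of its dcp5-1 reads were antisense, so its ratio does not measure mRNA fragments alone. Seed storage protein genes, a check for later stages, had no member with enough reads, and of 6 tapetum and pollen coat genes only GRP17 did, at -1.51 (-2.83 to -0.31).

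The abundance of mature miRNAs was compared next. Reads identical to the listed mature miRNA sequences summed to 38139 RPM in wild type and 29431 in dcp5-1, a log2 ratio of -0.37 (-0.38 to -0.37). Of 53 mature sequences with at least 50 reads over both libraries, 51 were lower in dcp5-1, 39 of them with an interval below 0, and none of the 53 had an interval above 0. The median log2 ratio was -0.49. A difference of at least 2-fold was seen for 11 sequences, all lower, and for 0 higher. The most abundant miRNA, miR172c,d, which targets APETALA2-type floral regulators, had a ratio of -0.015 (-0.027 to -0.0019), at 11705 RPM in wild type and 11588 in dcp5-1. The next most abundant were miR159a, which targets MYB transcription factors (-0.55, -0.57 to -0.54), miR158a (-0.49, -0.51 to -0.46) and miR164a,b, which targets NAC transcription factors (-0.46, -0.49 to -0.43). The largest differences were those of miR169h-n (-2.13, -3.20 to -1.18, on 41 and 12 reads), miR408 (-1.69, -1.83 to -1.55) and miR396a, which targets growth-regulating factors (-1.36, -1.64 to -1.09). Chosen after the values were seen, miR156a-f, which targets SPL transcription factors, had 1072 RPM in wild type and 507 in dcp5-1 (-1.08, -1.13 to -1.03). All 9 measured passenger strands were also lower, with a median of -0.70. Without miR172c,d the summed ratio was -0.57.

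**Figure D2:**
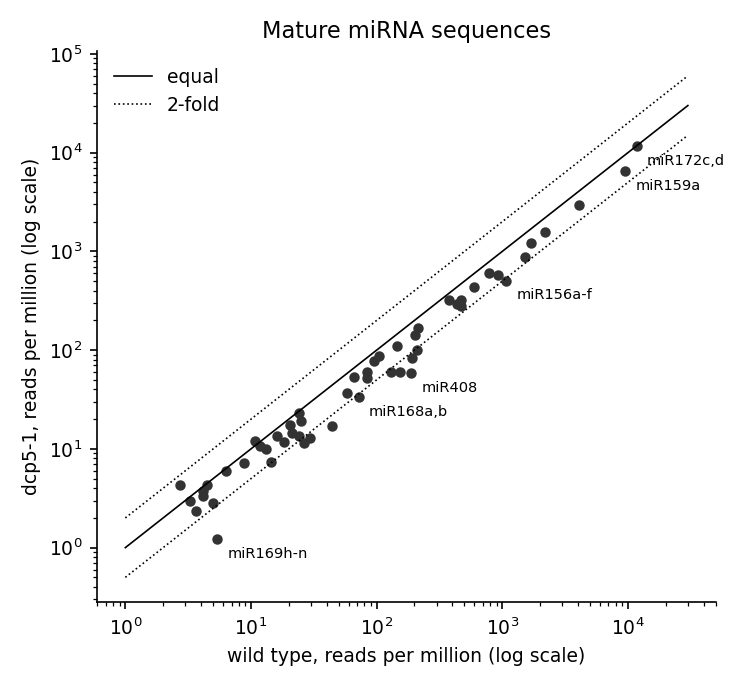
Each point is 1 of the 53 mature miRNA sequences with at least 50 reads, with RPM in wild type on the x axis and in dcp5-1 on the y axis, both on log scales. The solid line marks equal levels and the dotted lines 2-fold differences; 51 points lie below the solid line and 11 at or below the lower dotted line.

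The TAS loci, whose transcripts are cut by a miRNA and diced into phased ta-siRNAs, were examined in the same way. Their 21-nt reads were lower in dcp5-1, with a log2 ratio of -0.28 (-0.31 to -0.26), which was -0.44 with TMM factors and -0.11 (-0.23 to 0.013), with an interval that holds 0, for distinct sequences at equal depth. All 7 measured TAS loci were lower for reads of all sizes, and their median of -0.42 lay at percentile 2.60 of matched random lists. TAS2 (AT2G39681, chromosome 2, 16539384 to 16540417) had a ratio of -0.21 (-0.25 to -0.17), TAS1C of -0.24 (-0.28 to -0.20), TAS1A of -0.43 (-0.50 to -0.35) and TAS1B of -0.42 (-0.52 to -0.33). TAS3A, whose ta-siRNAs target auxin response factor genes, had a ratio of -0.42 (-0.47 to -0.37), TAS3B of -0.14 (-0.24 to -0.046) and TAS3C of -0.65 (-0.98 to -0.32). TAS4 had 0 reads in both libraries. The most used of the 21 registers over both libraries held 58.2% (56.1 to 60.4) of the TAS1A 21-nt reads in wild type and 53.0% (50.8 to 55.1) in dcp5-1, and 47.3% (46.1 to 48.4) and 46.1% (45.0 to 47.3) at TAS2. At TAS3C the share was 59.4% (50.9 to 67.4) in wild type and 35.1% (26.3 to 45.0) in dcp5-1. At TAS3B it was 11.0% (9.35 to 13.0) in wild type, where another register was the most used, and 15.3% (13.5 to 17.3) in dcp5-1. This register was the most used in dcp5-1 only, so the TAS3B shares do not show a rise in phasing. At TAS1B the shares were 35.4% and 29.3%, at TAS1C 26.7% and 24.5% and at TAS3A 33.4% and 27.7%.

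Genes known to give secondary siRNAs were grouped by type. Of 15 measured pentatricopeptide repeat genes, which share many siRNA sequences among near-identical copies, 13 were higher in dcp5-1 and 2 lower, with a median of 0.20 at percentile 73.6; with TMM factors 10 were higher and 5 lower. AT1G62910 had a ratio of 0.31 (0.21 to 0.40) and AT1G12775 of 0.70 (0.31 to 1.09). AT1G63130 had 0.12 (-0.0015 to 0.24), which changed sign to -0.043 with TMM factors. Among 7 measured other targets of miRNAs or ta-siRNAs, 3 were at least 2-fold higher and the median was 0.61, at percentile 95.6. These 3 were the auxin receptor genes TIR1 (AT3G62980; 1.93, 1.21 to 2.73) and AFB2 (AT3G26810; 1.50, 1.19 to 1.82) and the auxin response factor gene ARF2 (1.51, 0.85 to 2.23; 1.55 from counts that were not rounded). At TIR1 a single sequence held 67.9% of the 21-nt reads in dcp5-1. AFB3, another auxin receptor gene, which overlaps another annotated gene, had 0.61 (0.36 to 0.86), AGO1 had -0.32 (-0.65 to 0.0093) and ARF4 had -0.44 (-1.02 to 0.13). The 3 measured NBS-LRR disease resistance genes were all below 0, with a median of -0.12 at percentile 23.8. The intervals of AT5G43730 (-0.12, -0.69 to 0.45) and AT5G43740 (-0.016, -0.43 to 0.40) held 0. AT1G12290, which holds the miR472 sequence of an overlapping MIR gene on its own strand, had -0.44 (-0.54 to -0.34). Its reads in dcp5-1 were 0% antisense, so siRNAs of this gene cannot be told apart from reads of the MIR gene.

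A list of genes at which siRNAs arise when mRNA decay is impaired had 2 measured members, both higher in dcp5-1. SMXL4 (AT4G29920, chromosome 4, 14632413 to 14636101), a gene acting in phloem formation, had 5 reads in wild type and 110.5 weighted reads in dcp5-1, a log2 ratio of 4.10 (2.83 to 5.75) from rounded counts and 4.11 without rounding. SMXL5, its close relative, had 2 and 38 reads (3.89, 1.94 to 6.98). The median of these 2 related genes was at percentile 100 of matched random lists, but both passed the minimum of 20 reads only through their dcp5-1 reads. The other members, the nitrate reductase genes NIA1 and NIA2, had 7 and 8 reads over both libraries and were not measured. NIA1 had 4 reads in wild type and 3 in dcp5-1, and NIA2 had 1 and 7. None of the 12 decapping and decay genes had 20 reads. Of 5 measured small RNA pathway genes, 3 were above and 2 below 0 (median 0.14, percentile 45.3), and with TMM factors 2 were above and 3 below (median -0.018). DCL1, which makes miRNAs and holds the miR838 sequence of an overlapping MIR gene on its own strand, had -0.72 (-1.27 to -0.18). DCL4 had 0.55 (-0.78 to 1.99), or 0.46 from counts that were not rounded. AGO10 had 0.21 (-0.37 to 0.81) and AGO2 0.13 (-0.42 to 0.68), which became -0.035 with TMM factors. The 3 measured genes with RNA-directed DNA methylation at their promoters had a median of -0.051 (percentile 24.4), with FWA at -0.048 (-0.30 to 0.21), SDC at -0.22 (-0.59 to 0.14) and ROS1 at 0.28 (-0.062 to 0.63).

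Over all annotated nuclear genes, 5647 had at least 100 weighted reads of 18 to 28 nt. Of these, 319 were at least 2-fold higher and 243 at least 2-fold lower in dcp5-1, against 196 and 327 with TMM factors. With 1-hit reads only, 116 were lower, while with full counts at every hit more than 243 were. Genes annotated as pseudogenes held 219 of the higher genes and 5 of the lower, among 2824 measured (123 and 6 with TMM factors). Those annotated as transcribed pseudogenes, a separate type, held 18 and 5 among 233 (15 and 8 with TMM factors), and tRNA genes held 93 of the lower genes among 241. Sense reads of protein-coding genes had a log2 ratio of 0.086 (0.081 to 0.091), which became -0.074 with TMM factors. Their 21-nt sense reads had 0.28 (0.26 to 0.30) and their 21-nt antisense reads 0.30 (0.28 to 0.32), against 0.12 and 0.14 with TMM factors. Their 22-nt reads were lower, at -0.062 for sense and -0.12 for antisense reads. The 21-nt reads of pseudogenes of both types had 0.41, or 0.25 with TMM factors.

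The 3 genes with the highest ratios among those with at least 500 reads were protein-coding and had mainly 21-nt reads, on both strands, in dcp5-1. KCS1 (AT1G01120, chromosome 1, 57164 to 59215), which acts in the elongation of very long chain fatty acids, had 3 reads in wild type and 567 in dcp5-1, a log2 ratio of 7.20 (5.65 to 9.48). CER3 (AT5G57800, chromosome 5, 23420184 to 23424117), which acts in wax synthesis, had 17.2 and 1042 reads (5.58, 4.89 to 6.36). AT5G20700 (chromosome 5, 7005667 to 7007502) had 25 and 1335 reads (5.38, 4.81 to 6.01). In dcp5-1, 21-nt reads made up 79.5% of the KCS1 reads, 79.0% of the CER3 reads and 79.8% of the AT5G20700 reads. All of these reads lay in annotated exons, with 91.5%, 97.1% and 66.5% in coding sequence, and 35.2%, 69.1% and 41.8% were antisense. The next 5 were the long noncoding RNA gene AT1G07493 (2.14, 1.81 to 2.48), the pseudogene AT4G06538 (1.98, 1.67 to 2.30) and the transcribed pseudogenes AT5G29030 (1.99, 1.79 to 2.19), AT4G06582 (1.92, 1.65 to 2.21) and AT5G29040 (1.87, 1.60 to 2.15), at which most reads were 24 nt long.

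**Figure D3:**
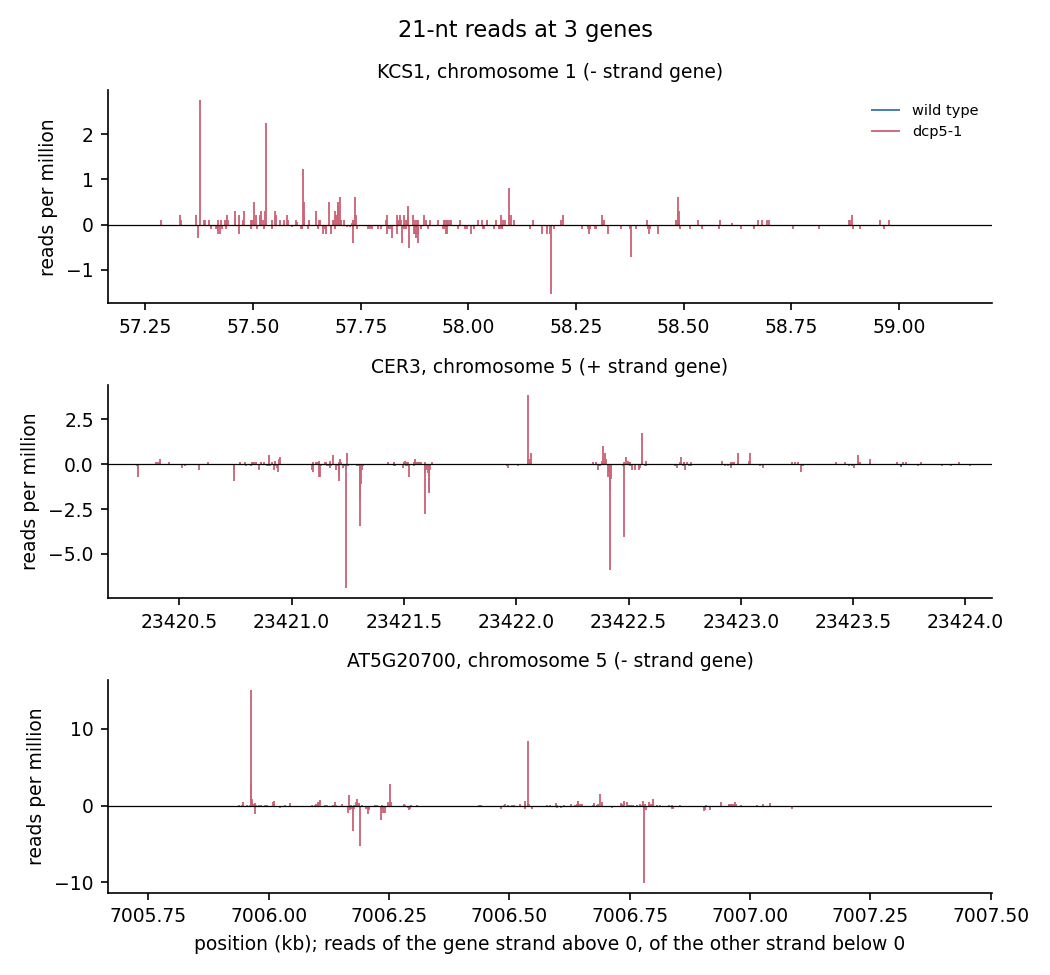
21-nt reads along KCS1, CER3 and AT5G20700, with the position in kb on the x axis and RPM on the y axis, reads of the gene's strand above 0 and of the other strand below. The dcp5-1 reads lie along the genes on both strands; the wild-type library had 1, 11 and 16 such reads at the 3 genes.

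The lowest ratios were those of loci with 24-nt reads. At AT2G32291, a transcribed pseudogene (chromosome 2, 13717189 to 13717655), 3315 reads in wild type stood against 54 in dcp5-1, a log2 ratio of -6.30 (-6.72 to -5.91), and 1 start position held 74.2% of the wild-type reads. AT4G03824, a pseudogene (chromosome 4, 1782462 to 1783625), had 537 and 17 reads (-5.34, -6.13 to -4.65). AT3G07775, a long noncoding RNA gene that overlaps another gene (chromosome 3, 17520412 to 17521027), had 977 and 34 reads (-5.20, -5.74 to -4.71). XBAT34 (AT4G14365, chromosome 4, 8271270 to 8273903), of a family of ankyrin-repeat ubiquitin ligases, had 712 and 27 reads (-5.08, -5.69 to -4.53), all in exons and 76.4% antisense in wild type, with none in its coding sequence. In wild type the middle 90% of reads at each of these loci had their midpoints in a short stretch. It ran from 13717357 to 13717419 at AT2G32291, 1783140 to 1783185 at AT4G03824, 17520447 to 17520531 at AT3G07775 and 8271388 to 8271429 at XBAT34. Antisense reads in wild type were 90.7% at AT2G32291, 2.61% at AT4G03824 and 80.9% at AT3G07775. AT1G12020 followed at -2.45 (-2.78 to -2.12), AT1G08955 at -2.22 (-2.54 to -1.91), COQ3, which acts in ubiquinone synthesis and had 8.80% of its wild-type reads in exons, at -1.95 (-2.17 to -1.73), and AT5G00720 at -1.74 (-1.92 to -1.57).

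The reference annotates practically no transposable elements, so 24-nt reads were summed over gene-poor 100-kb windows, with fewer than 10 protein-coding genes each. These 163 windows held 24-nt reads at 132920 RPM in wild type and 169009 in dcp5-1, a log2 ratio of 0.35 (0.34 to 0.35), or 0.19 with TMM factors. Nuclear 24-nt reads outside them had 0.060 (0.059 to 0.062), or -0.10 with TMM factors. Of 9114 5-kb windows with at least 100 24-nt reads, 237 were at least 2-fold higher and 231 at least 2-fold lower in dcp5-1, against 123 and 293 with TMM factors. Full counts at every hit also gave 123 higher windows. Of the 237 higher windows, 186 lay in gene-poor regions, and of the 231 lower ones 228 lay outside them, against 92 and 288 with TMM factors. The median log2 ratio was 0.40 over 2984 windows in gene-poor regions and -0.016 over 6130 others. The 5 highest windows with at least 500 reads were all gene-poor. On chromosome 5 they began at 11095001 (1.82, 1.51 to 2.14), 11135001 (1.78, 1.51 to 2.07) and 11105001 (1.71, 1.41 to 2.02), on chromosome 2 at 3935001 (1.74, 1.58 to 1.91) and on chromosome 3 at 12795001 (1.72, 1.46 to 1.99). The lowest were on chromosome 4 at 8270001, which holds XBAT34 (-5.45, -6.30 to -4.72), on chromosome 3 at 17520001, which holds AT3G07775 (-5.03, -5.63 to -4.48), on chromosome 4 at 7795001, by ATCSLA15 and the potassium transporter gene HAK5 (-4.23, -4.64 to -3.85), on chromosome 2 at 1175001 (-3.92, -4.30 to -3.57) and on chromosome 4 at 1780001, which holds AT4G03824 (-3.77, -4.25 to -3.32).

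**Figure D4:**
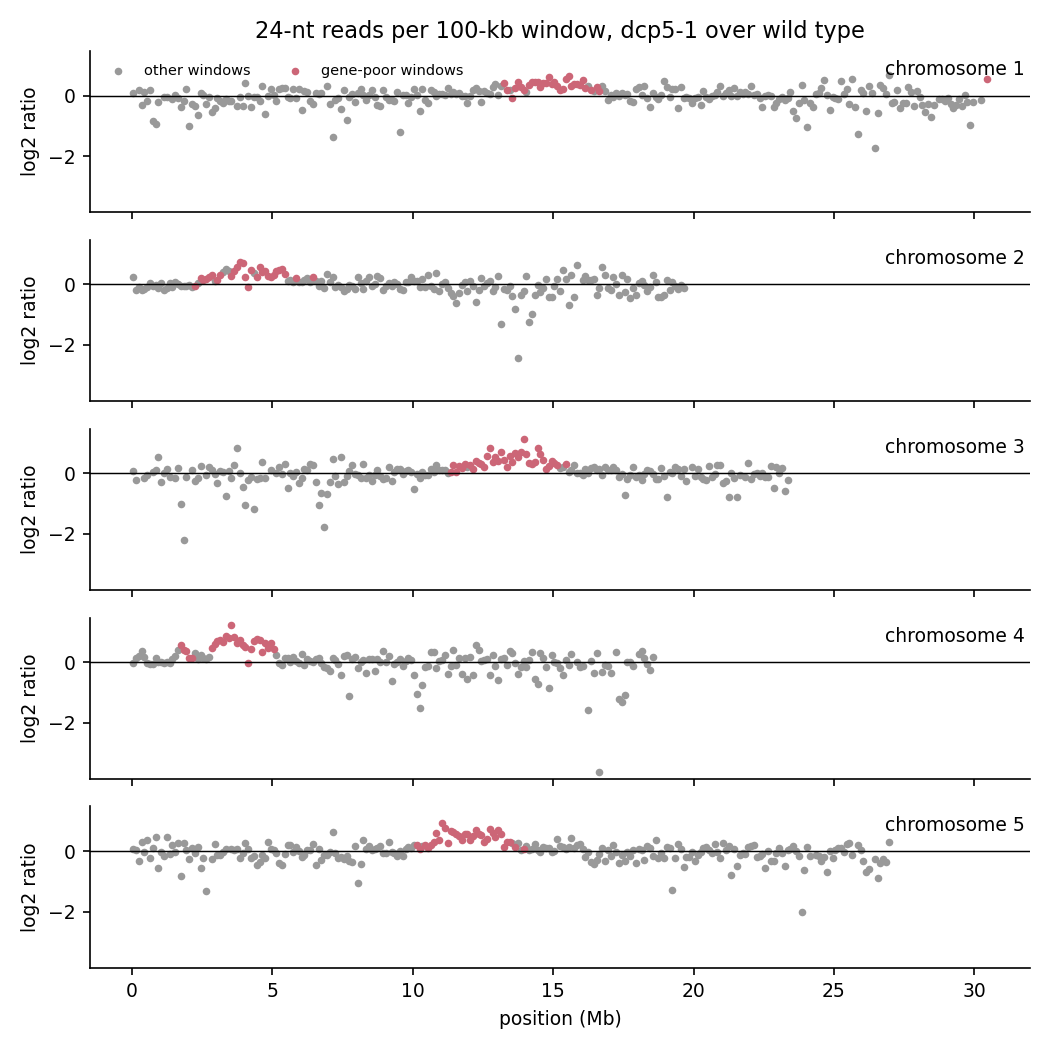
Each point is a 100-kb window with at least 100 24-nt reads, with its position in Mb on the x axis and the log2 ratio of dcp5-1 over wild type on the y axis, for the 5 nuclear chromosomes. Gene-poor windows, coloured, lie mostly above 0; summed over them the ratio was 0.35.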

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

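Reads outside the comparisons of the report are given here. Reads with 1 or 2 mismatches entered only an alternative setting and the test of sequence variants. In the dcp5-1 library 22.8% of all reads matched the genome nowhere, and in the wild-type library 19.5% did. Reads that matched only with 1 or 2 mismatches were 7.95% of the dcp5-1 library and 7.86% of the wild-type library. At the positions of the listed mature miRNAs, reads with 1 mismatch were counted against mature reads and 1-mismatch reads together. Their share was 6.40% (6.31 to 6.49) in dcp5-1 and 5.68% (5.60 to 5.76) in wild type. No explanation was tested for these values.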

How the results depend on the processing

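No paired analysis was possible because each genotype had 1 library and no result comes from a test; leaving out a library is likewise not possible. Values are log2 ratios of dcp5-1 over wild type or counts. The alternatives with up to 2 mismatches, with rRNA flanks, and for 21-nt reads of genes were chosen after seeing the data. For the values below the cause was not tested, except where fewer reads, genes or windows enter by construction. Of the ratios of read classes listed below, 3 turned direction under an alternative: 21-nt reads were 0.13 as distinct sequences at equal depth, and with TMM factors 24-nt reads were -0.033 and protein-coding sense reads -0.074. Other values turned with TMM factors too, among them 24-nt reads outside gene-poor windows (-0.10), protein-coding antisense reads (-0.083), the median of all genes (-0.027) and that of small RNA pathway genes (-0.018).

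Scaled to all reads, the ratio was -0.19 for 21-nt reads, 0.11 for 24-nt reads, -0.39 for miRNA reads, 0.33 for 24-nt reads of gene-poor windows, 0.067 for protein-coding sense reads and -0.52 for structural RNA. Scaled to reads outside structural RNA and organelles, in the same order with TAS 21-nt reads after miRNA, it was -0.23, 0.066, -0.44, -0.34, 0.29, 0.025 and -0.57. With TMM factors it was -0.33 for 21-nt, -0.53 for miRNA, -0.44 for TAS 21-nt, 0.19 for gene-poor 24-nt and -0.67 for structural RNA reads, and 196 genes and 123 windows were at least 2-fold higher. As distinct sequences, 24-nt reads had 0.039, TAS 21-nt reads -0.11 (-0.23 to 0.013), gene-poor 24-nt reads 0.25, protein-coding sense reads 0.010 and structural RNA -0.49. For miRNA reads it was -0.011 (-0.52 to 0.49), but this counts only which listed sequences are present and cannot show a change in their level. Without the most abundant sequence, 21-nt reads had -0.20, miRNA reads -0.57 and structural RNA -0.56.

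With 1-hit reads only, gene-poor 24-nt reads had 0.34, protein-coding sense reads 0.10 and structural RNA -0.60, and 116 genes were at least 2-fold lower. With full counts at every hit these were 0.40, 0.092 and -0.75, with 420 genes lower and 123 windows higher. miRNA isoforms gave -0.39, 24-nt reads with up to 2 mismatches 0.13 and structural RNA with rRNA flanks -0.50. Of the genes, windows and miRNAs named one by one, AT1G63130 and AGO2 changed sign, both with TMM factors. Without rounding of weighted counts, an alternative added after seeing the data, the ratios of all 128 stayed within their intervals, and the largest shift was 0.087, at DCL4. At 5 times the minimum, 122 genes were higher and 92 lower, and 115 windows higher and 51 lower. At a minimum of 10 reads, 2 miRNAs were higher, 1560 genes higher and 777 lower, and 356 windows higher and 669 lower. At this depth, genes and miRNAs with few reads carry wide intervals, so such counts at low minimums hold much counting error.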

Other observations

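The tests below on 21-nt reads of protein-coding genes, upstream frames included, on the 4 loci with lost 24-nt reads and on gene-poor against other windows were chosen after the result was seen, but the outcomes of the 1-hit test on the 61 genes and of the mismatch test were stated first, and the 1-hit and distinct-sequence settings for gene-poor windows were chosen before the data were examined but read as tests only after their values were known. Among 610 protein-coding genes with at least 30 21-nt reads over both libraries and no overlap with a MIR, TAS or structural RNA gene, 61 were at least 4-fold higher in dcp5-1 and 3 at least 4-fold lower, while at 2-fold it was 145 against 24. The median log2 ratio of the 610 genes was 0.17, with 368 above 0 and 242 below, and 0.0077 with TMM factors, with 309 above and 301 below. At 4-fold it was 51 against 4 with TMM factors, and minimums of 20, 50 and 100 reads gave 116, 35 and 10 higher genes against 5, 2 and 1 lower. None of the 61 higher genes had more than 17.5 21-nt reads in wild type (LRX3). Each thus reached the minimum of 30 reads only with its dcp5-1 reads. The genes named here were chosen after their values were seen. Besides KCS1, CER3 and AT5G20700, the genes with the highest ratios, 0.5 added to each count, were AT4G23870 (1 and 123 21-nt reads) and EBF1 (2 and 198), an F-box gene of ethylene signalling. The set also held the receptor kinase genes BAM1 (4 and 92.5) and BRI1 (7 and 42.5), the auxin response factor gene ARF6 (11 and 144), and the arginine decarboxylase genes ADC1 (2 and 29) and ADC2 (17 and 141).

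Not all of the 61 genes had mainly 21-nt reads: AT5G29070, AT5G32590 and AT4G06688 had more 24-nt than 21-nt reads in dcp5-1 and held 897 of the 1137 24-nt reads of the set, and without them 58 genes were left. Fragments of broken mRNA would lie on the sense strand, but 51.2% of the 21-nt reads of the 61 genes in dcp5-1 were antisense, and 51.1% (49.8 to 52.4) of those of the 58. Of the 61 genes, 8 overlapped another annotated gene, whose own reads can count as antisense there. By gene the median antisense share was 53.8%, and all 61 genes were above 10%. The share was low at some genes, such as AT4G23870 (12.2%) and BAM1 (17.3%), where fragments are not set aside. A single abundant sequence does not account for the set as a whole, as the most abundant one held a median of 10% of a gene's 21-nt reads, with TIR1 (67.9%) the only gene above 50%, and with 1-hit reads only, which paralogs do not share, 100% of the genes stayed at least 4-fold higher. With 1 library per genotype, a difference between the libraries other than the genotype cannot be told apart from an effect of dcp5-1, which also stays untested.

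A further hypothesis was that genes with an annotated upstream open reading frame gain more 21-nt reads than genes of like level. The reference annotates such frames for 84 genes, of which 23 had at least 10 21-nt reads; their median log2 ratio was 2.09, against 0.44 for the other genes, and lay at percentile 100 of 10000 matched random lists (95% of those between 0.012 and 1.20). At a minimum of 30 reads, 9 of 13 such genes were at least 4-fold higher; at 20 it was 9 of 15, at 50 it was 5 of 7 and at 100 it was 3 of 3. VTC2 (0 and 30.5), BZIP53 (1 and 40.5), bZIP44 (3.5 and 60), GBF6 (11.5 and 96) and SAMDC (15 and 107) were among them. Of the 9 higher genes, SAMDC had the most 21-nt reads in wild type. All 9 thus passed the minimum of 20 or more only with their dcp5-1 reads, and the counts at different minimums share genes. The hypothesis came from reading the names of the genes with high ratios, so these same data cannot test it independently. Fisher's exact tests at minimums of 20, 30 and 50 reads were also tried while it was formed; their p-values are not given, since genes are not replicates.

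The near loss of 24-nt reads at AT2G32291, AT4G03824, AT3G07775 and XBAT34 was weighed next. A deletion with no other reads in the library would leave 0 uniquely matching reads, but the fewest at any of the 4 loci was 17. If wild-type reads with the locus profile of this library had been mixed in, the residual share of 24-nt reads would be the same everywhere. Its upper bound at AT2G32291, the lowest locus, was 1.64%, and the lower bound at AT3G07775 was 1.94%, so these bounds lay apart. At AT2G32291, AT4G03824 and XBAT34 this was not so for 24-nt reads (lower bounds up to 1.56%). Over all sizes, where the shares were first compared, XBAT34 lay apart too (1.93%, against an upper bound of 1.66%). The bounds cover counting error only, on 47 dcp5-1 24-nt reads at AT2G32291 and 27 at AT3G07775, so small gaps between them cannot decide. At all 4 loci a deletion with mixed-in reads cannot be told apart from a loss of siRNAs. Sparse sequence variants in the mutant would turn perfect reads into reads with 1 or 2 mismatches. In dcp5-1 such reads at the 4 loci came to 0.112% (0.049 to 0.222) of the wild-type perfect reads. Variants that leave no hit within 2 mismatches could not be seen and stay untested. A difference between plant lots, such as an epigenetic one, stays untested too.

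For the gain of 24-nt reads in gene-poor windows, sharing of multi-hit reads between repeats would remove it among 1-hit reads, where the log2 ratio was 0.34. A few abundant sequences would remove it among distinct sequences at equal depth, where it was 0.25, and a smaller share of other sizes would raise 24-nt reads everywhere, but against 24-nt reads outside gene-poor windows it was 0.29 (0.28 to 0.29). With TMM factors the ratio was 0.19. Differences in the stage or makeup of the buds stay open, with chloroplast reads at -1.17 on the log2 scale, and the genotype may equally be the source.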
